A study of Mus musculus with 9 samples.

How the data were processed

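The series holds single-nucleus RNA sequencing of hearts from 9 mice, 1 library per mouse. Per the labels, 3 mice were homozygous for a cardiomyocyte-specific knockout allele of Terf2 (f,f), 3 were heterozygous (f,+) and 3 were controls (+,+). They are called here control mice 1, 2 and 3, homozygous mice 4, 5 and 6, and heterozygous mice 7, 8 and 9. Terf2 encodes TRF2, a protein of the shelterin complex that caps telomeres. Nuclei were loaded on the 10x Genomics platform, version 3.1, which counts RNA from the 3′ end. The labels give no age, date or batch, and they name goblet cells as the cell type of every heart library. No goblet cell marker passed the low-count filter in any of the 6 cell types compared. Xist stood between 0.355 and 2.07 normalised counts (CPM) and the Y-linked gene Uty between 194 and 253 CPM, so all 9 mice were read as male and no sex term was fitted.

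The authors deposited raw UMI counts per gene and barcode, without normalisation and with barcodes already limited to called cells. The submitters' processing notes name Cell Ranger 7.0.1, Seurat 4.0.0 and genome build mm10. They do not state the annotation release, the use of intronic reads or the settings of the cell calling. The matrices held whole numbers from 1 upward, 13702 to 19930 barcodes per library and 441912277 UMIs in total. The smallest number of UMIs of a barcode was 500 in 5 libraries and between 861 and 1079 in the other 4, so the calling had not stopped at 1 level. Gene positions come from GENCODE release M21 on GRCm38, in which 32235 of the 32285 gene identifiers were found.

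Nuclei were kept with at least 300 genes, at least 500 UMIs and at most 10.0% mitochondrial UMIs. This left 125738 of 152997 barcodes, 9708 to 16916 per mouse. The mitochondrial limit removed 27259 barcodes, from 2.97% of them in heterozygous mouse 7 to 29.2% in control mouse 2, and the other limits removed 2. Doublets were scored per library with scrublet in scanpy 1.11.5 (anndata 0.12.19, Python 3.11.15). Its automatic threshold was used where it marked between 0.5% and 30.0% of a library, which held for control mouse 3 and heterozygous mouse 9. In the other 7 libraries the nuclei with the highest scores were taken up to an expected rate of 0.8% per 1000 nuclei. In all, 15468 doublets were called, 4.43% to 26.0% of a library. All kept nuclei were scaled to 10000 counts, log-transformed and clustered once without integration, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Of 39 clusters, 19 were named as 15 cell types from 19 fixed marker lists. A further 14 clusters carried markers of 2 types and were left out with the doublets, and 6 stayed unnamed. The named types held 89296 nuclei. The clusters of 2 types held 18001 nuclei, on average 15.9% in control, 14.6% in heterozygous and 18.9% in homozygous mice (exact permutation p = 0.836 among genotypes). The unnamed clusters held 2973 nuclei (exact permutation p = 0.268).

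Counts were summed per mouse and cell type, so that the mouse is the replicate (n = 3 per genotype). Cardiomyocyte sums held 374 to 1533 nuclei and 2305506 to 6668294 UMIs per mouse, 7051 nuclei in all. Fibroblast sums held 2746599 to 4672218 UMIs, endocardial sums 2135533 to 8780755, endothelial sums 1390370 to 2764556, macrophage sums 660270 to 1980269 and pericyte sums 204480 to 507900. Each mouse gave at least 142 nuclei to each of the 6 types. Genes were filtered with filterByExpr and tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and dispersions shared by the 3 genotypes. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05. Standard errors of log2 fold changes were derived from the F statistic. The comparisons were homozygous with control, heterozygous with control, homozygous with heterozygous, and in cardiomyocytes also the 3 genotypes together. Normalised levels are CPM with the TMM factors, given as mean ± SD over 3 mice, and log2 fold changes as value ± SE. Where a level is compared between cell types, CPM were taken from the plain sums of each type.

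On simulated data with 200 changed genes, drawn to the depth of each mouse and the mean and dispersion of each gene, the cardiomyocyte comparison recovered 65.7% of changes of 1 log2 unit and 89.8% of changes of 2 log2 units, with 13 false among 166 calls. It called 0 genes in the comparison simulated without change, by the same edgeR test. At 1 log2 unit the recovery was 59.0% in fibroblasts, 76.8% in endothelial, 69.7% in endocardial, 45.8% in pericyte and 45.4% in macrophage nuclei. The test of the difference between cardiomyocytes and fibroblasts recovered 59.8% with 7 false among 141 calls.

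The 27 gene lists, numbered 1 to 27, were tested with camera at a preset correlation of 0.01, BH-adjusted over the lists of 1 comparison, then with an estimated correlation (values marked estimated), and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. Marker lists of other cell types were tested in the same way as a family of their own. The free RNA of a heart is shared by all its droplets, so a gene with a low level in a type and a high level in another is given with its level in the type that holds most of it. A gene was treated as coming from other cells where its mean CPM in cardiomyocytes was under 1/3 of that in all other named nuclei, or in another type under 1/3 of that in cardiomyocytes. Shares of cell types were tested by exact permutation of the between-group F statistic over the 280 splits of 9 mice into 3 groups of 3, with a smallest p of 0.00357, and BH-adjusted over the 15 types. Comparisons of 3 with 3 mice have 10 splits, and their exact two-sided permutation test cannot give a p under 0.1. Calculations used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

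Genes were named by a fixed rule. In cardiomyocytes of homozygous and control mice these are Terf2, the 10 largest called rises and the 10 largest called falls with a mean of at least 10 CPM, a symbol other than a clone name, and 3 mice of 1 genotype all outside the range of the other 3, then up to 4 members of each list with the lowest adjusted p. In the other comparisons of cardiomyocytes the rule took 5 and 5. In other types it took 4 and 4, without genes whose level was under 1/3 of that in cardiomyocytes, and up to 3 members of each list that fits the type. The groups, the tests, the 27 lists, the marker lists, the rule and a first set of alternatives were fixed before the data were examined. Further members of lists that are named because they passed the test or mark another cell type were chosen after their values were seen.

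The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no low-count filter, each mouse left out in turn, doublets kept, at most 5% mitochondrial UMIs, at least 1000 UMIs, counts thinned to the smallest library, and only the 6 mice compared. Chosen after seeing the data were the comparison of endocardial nuclei, the UMIs per nucleus, the test of a difference between cardiomyocytes and fibroblasts, clock gene and ribosomal gene lists, and several alternatives. These took the expected doublet rate in every library, cardiomyocytes of 4000 to 9000 UMIs, the clusters of 2 types, a cluster rich in haemoglobin RNA, genes of other cells left out, at least 1100 UMIs, a wider denominator for the shares, and 1 endocardial cluster alone. Epicardial, lymphatic endothelial, smooth muscle and atrial nuclei were also compared gene by gene during the work and are not reported here. Not used were raw reads and droplets without a called cell, so free RNA was not measured directly and no correction for it was applied.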

Results

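Single-nucleus RNA counts were compared in the hearts of 9 male mice, 3 homozygous for a cardiomyocyte-specific Terf2 knockout, 3 heterozygous and 3 controls. The libraries held 48538081, 45818084 and 36148655 UMIs in control mice 1, 2 and 3. They held 60861522, 47201067 and 57969205 UMIs in homozygous mice 4, 5 and 6, and 47514503, 52871579 and 44989581 UMIs in heterozygous mice 7, 8 and 9. The median barcode held 1457 to 1820 UMIs and 1001 to 1168 genes. The named types held 7051 cardiomyocyte, 26899 endocardial, 19653 fibroblast, 12243 endothelial, 6536 macrophage and 1942 pericyte nuclei. The title of the series states an interest in loss of TRF2 and heart failure. The comparisons therefore ask what changed in cardiomyocytes with 1 or both Terf2 copies targeted, and in the cells around them.

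Terf2, the targeted gene, was counted in cardiomyocyte nuclei of every mouse, at 43.5, 37.7 and 40.8 CPM in control mice 1, 2 and 3. It stood at 31.5, 40.7 and 37.7 CPM in homozygous mice 4, 5 and 6 and at 43.1, 30.8 and 38.2 CPM in heterozygous mice 7, 8 and 9, from 101 to 248 UMIs per mouse. The log2 fold change was -0.15 ± 0.16 in homozygous against control mice (edgeR QL, BH-adjusted p = 0.690, exact two-sided permutation p = 0.2). It was -0.13 ± 0.16 in heterozygous against control mice (edgeR QL, BH-adjusted p = 0.806, exact p = 0.6). It was -0.02 ± 0.15 between homozygous and heterozygous mice (edgeR QL, BH-adjusted p = 0.959, exact p = 0.9). Terf2 in cardiomyocytes less that in all other named nuclei of the same mouse was -0.33 ± 0.04 (SD, n = 3) in control, -0.35 ± 0.21 in heterozygous and -0.30 ± 0.16 in homozygous mice on the log2 scale (exact permutation p = 0.889 over the 3 genotypes). Terf2 (ENSMUSG00000031921) lies on the minus strand of chromosome 8 at 107069400 to 107096547 (GRCm38). The labels do not name the deleted exons, and counts from the 3′ end can lie outside a deleted part, so these values check neither the genotype labels nor the deletion. The 7 shelterin genes (gene list 1) held 0 calls in any comparison of cardiomyocytes. Their list gave camera adjusted p = 0.732, 0.609 and 0.385 for homozygous against control, heterozygous against control and homozygous against heterozygous mice. The 10 tested neighbours of Terf2 on the chromosome (gene list 2) also held 0 calls, with adjusted p = 0.758, 0.999 and 0.732. In heterozygous mice their median of 0.05 and mean of 0.03 differed in sign from the test.

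**Figure D1:**
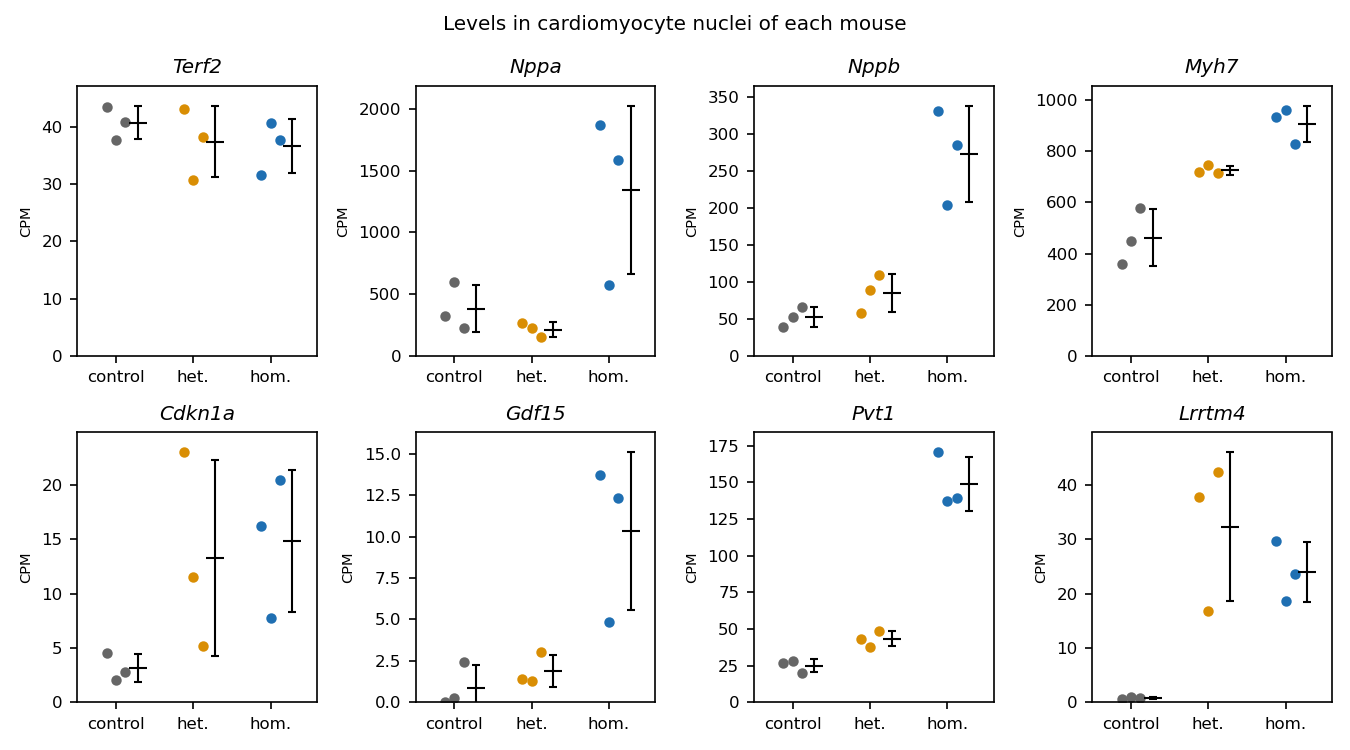
Levels of 8 genes in cardiomyocyte nuclei in CPM (y axis) by genotype (x axis, het. heterozygous, hom. homozygous). Points are mice, bars mean ± SD of 3 mice without the part below 0, and Pvt1 stood at 149 ± 18.4 CPM in homozygous against 25.1 ± 4.29 CPM in control mice while Terf2 overlapped.

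Cardiomyocytes of homozygous mice, in which both Terf2 copies were targeted, had more Lrrtm4, Dpp10 and Ptgds RNA than in controls and less Clcn1 and Mme RNA. Lrrtm4, a synaptic adhesion protein, stood at 24.01 ± 5.58 CPM against 0.809 ± 0.240 CPM in controls, a log2 fold change of 4.83 ± 0.51 (SE, n = 3 and 3). Dpp10, a partner of potassium channels, rose by 4.56 ± 0.31, from 1.09 ± 0.462 to 24.7 ± 3.48 CPM. Ptgds, a prostaglandin D synthase, reached 1128 ± 313 CPM against 159 ± 48.3 CPM, a rise of 2.83 ± 0.31. The chloride channel gene Clcn1 fell by 2.51 ± 0.27, to 6.01 ± 3.04 from 34.5 ± 4.90 CPM, and Mme, the membrane peptidase neprilysin, fell by 2.31 ± 0.20, to 4.21 ± 0.507 from 21.04 ± 2.51 CPM. In all, 561 of 13681 genes were called, 279 higher and 282 lower (edgeR QL, BH), with adjusted p = 2.18e-04 for Lrrtm4, 8.01e-06 for Dpp10, 2.89e-04 for Ptgds, 2.68e-04 for Clcn1 and 1.00e-04 for Mme. The 10 largest rises under the naming rule were those of Lrrtm4, Dpp10, Tenm2, Ryr3, Gpc5, Mgat4c, Galntl6, Nrg1, Ptgds and Cntnap2, from 4.83 down to 2.76. The 10 largest falls were those of Clcn1, Mme, Tox, Nkain4, Alas2, Map2k6, Dbp, Efnb3, Epb41l4b and Rarres2, from -2.51 to -1.76. The rule took only genes whose 3 homozygous mice lay outside the range of controls, which chance gives for 10% of genes. Lrrtm4 (ENSMUSG00000052581) spans 80018877 to 80810143 on chromosome 6 and Dpp10 (ENSMUSG00000036815) 123321471 to 124045559 on chromosome 1. Several were higher in another type, where Nrg1 stood at 5488 CPM in endocardial nuclei of homozygous mice and 1280 CPM in those of controls. Rarres2 stood at 862 and 1188 CPM in epicardial nuclei. Tenm2 stood at 772 CPM in atrial cardiomyocytes of homozygous mice and 23.2 CPM in those of controls. The count of 561 became 350, 274 and 351 without control mice 1, 2 and 3, 319 and 278 without homozygous mice 4 and 6, and 164 among nuclei of 4000 to 9000 UMIs. In that UMI range Tenm2, Gpc5, Mgat4c, Cntnap2 and Efnb3 lost their calls, with adjusted p from 0.0769 to 0.221, against 1.48e-38 at the lowest over all alternatives. Nkain4 lost it there, with the clusters of 2 types, and without control mouse 3 or homozygous mouse 6 (adjusted p from 0.0610 to 0.0841).

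Of 26 target genes of the tumour suppressor p53, 7 rose in homozygous cardiomyocytes and 19 did not pass. The long non-coding RNA gene Pvt1 rose by 2.56 ± 0.17, to 149 ± 18.4 from 25.1 ± 4.29 CPM, and Gdf15, a secreted stress factor, by 3.77 ± 0.73, to 10.3 ± 4.76 from 0.896 ± 1.33 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.22 ± 0.56, to 14.8 ± 6.51 from 3.16 ± 1.26 CPM, and its neighbour Trp53cor1 by 1.06 ± 0.20. Phlda3, Zmat3 and Perp were the other risers of this list (gene list 3), and 8 members rose over the list alone. Their adjusted p values were 8.01e-06 for Pvt1, 0.00927 for Gdf15, 0.0426 for Cdkn1a and 0.00839 for Trp53cor1 (edgeR QL, BH). The list as a whole was higher, with a median log2 fold change of 0.35, 22 members above 0 and camera adjusted p = 2.88e-09, against 0.223 estimated and 0.0117 by fry. Pvt1 (ENSMUSG00000097039) lies at 62037986 to 62378096 on chromosome 15, Gdf15 (ENSMUSG00000038508) at 70629393 to 70632456 on chromosome 8, and Cdkn1a (ENSMUSG00000023067) at 29090976 to 29100727 on chromosome 17. Other nuclei held these transcripts too, with Cdkn1a at 61.1 CPM in macrophages of homozygous and 25.1 CPM in those of control mice and Pvt1 at 281 and 266 CPM there. Pvt1 kept its call in 22 of 22 alternatives. Without control mouse 2 Gdf15 gave adjusted p = 0.0683 in a range of 2.71e-14 to 0.0683. In nuclei of 4000 to 9000 UMIs Trp53cor1 gave 0.209 in a range of 1.90e-04 to 0.209. Perp gave 0.0673 to 0.0808 without control mice 1 and 3 or homozygous mice 4 and 6. Cdkn1a lost its call in 9 of 22 alternatives with a range of 8.09e-12 to 0.176. It gave 0.0775, 0.176 and 0.132 without control mice 1, 2 and 3, 0.0970 and 0.144 without homozygous mice 4 and 6 and 0.0582 without heterozygous mouse 8.

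Natriuretic peptide genes and Myh7, among the genes that rise in stressed heart muscle, were also higher in homozygous cardiomyocytes. Nppb rose by 2.38 ± 0.25, to 273 ± 64.4 from 52.8 ± 13.4 CPM (edgeR QL, BH-adjusted p = 2.68e-04), and Myh7, the slow myosin heavy chain, by 0.97 ± 0.17, to 906 ± 70.0 from 462 ± 111 CPM (adjusted p = 0.00692). Of 19 cardiac stress genes (gene list 6) 7 rose, Nppa, Acta1, Rcan1, Pfkp and Flnc being the others, and over the list alone 12 rose and 2 fell. The list had a median of 0.67 and camera adjusted p = 9.75e-07, against 0.298 estimated and 0.0715 by fry. Nppa was as high outside ventricular cardiomyocytes, at 1367 CPM in cardiomyocytes, 1381 CPM in fibroblasts and 1897 CPM in endothelial nuclei of homozygous mice and 374, 605 and 735 CPM in those of controls. Acta1 stood at 145 CPM in cardiomyocytes and 229 CPM in fibroblasts of homozygous mice, against 45.2 and 53.6 CPM in controls. Nppb, with 278 CPM in cardiomyocytes and 125 CPM in fibroblasts, and Myh7, with 920 and 96.3 CPM, were higher in cardiomyocytes. Nppb (ENSMUSG00000029019) lies at 147985788 to 147987205 on chromosome 4 and Myh7 (ENSMUSG00000053093) at 54970684 to 54994626 on chromosome 14. Pfkp lost its call without control mice 2 and 3 and homozygous mouse 6 (adjusted p from 0.0744 to 0.0832), and Flnc without control mice 1 and 2 and homozygous mice 5 and 6 (0.0701 to 0.103). Over all alternatives Pfkp ranged from 8.91e-05 to 0.180 and Flnc from 0.00323 to 0.103.

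Genes of the respiratory chain were lower in homozygous than in control cardiomyocytes. Cox7a1, a muscle form of a cytochrome c oxidase subunit, fell by 0.96 ± 0.14, to 54.8 ± 9.29 from 106 ± 6.28 CPM (edgeR QL, BH-adjusted p = 0.00210). Cox8b fell by 0.81 ± 0.15 (adjusted p = 0.00715). Of 30 nuclear genes of oxidative phosphorylation (gene list 11) 5 fell, 6 over the list alone. Their median was -0.30, with camera adjusted p = 1.96e-08. With an estimated correlation this list and the 4 below each gave 0.761. The list was also lower in endocardial (-0.15, adjusted p = 0.0455), fibroblast (-0.13, 0.0295) and endothelial nuclei (-0.11, 0.0148), at least 0.659 estimated, not in macrophages (0.525) or pericytes (0.748). The 13 mitochondrially encoded genes (gene list 12) held 0 calls at a median of -0.40, with adjusted p = 0.00709. Among 19 potassium and sodium channel and gap junction genes (gene list 9) Kcnj3, a channel of atrial muscle, fell by 1.40 ± 0.21, to 238 ± 65.03 from 628 ± 127 CPM, and Kcnd2 fell by 0.79 ± 0.18. This list gave camera adjusted p = 0.00747. The integrated stress response (gene list 15) was higher with a median of 0.48 and 1 call of 18, Gdf15, and 3 over the list alone (adjusted p = 0.00389). Of the 16 resting fibroblast genes (gene list 21), 13 had a level in other nuclei over 3 times that in cardiomyocytes. They were lower with 2 calls, Smoc2 and Dpp4, and 4 over the list alone (adjusted p = 0.00389). Markers of atrial cardiomyocytes, epicardial cells and erythroid cells were lower in these same nuclei, at medians of -1.54, -1.15 and -1.75 (camera adjusted p = 3.49e-04, 1.29e-05 and 3.49e-04, and at least 0.352 estimated). Markers of 8 other types gave adjusted p from 0.455 to 0.925. Without control mouse 2 the channel genes gave adjusted p = 0.0678 and the mitochondrially encoded genes 0.146. The channel genes gave 0.0594 without homozygous mouse 6, the mitochondrially encoded genes 0.125 without control mouse 1, and the integrated stress response 0.0875 on thinned counts. Without homozygous mouse 5 the resting fibroblast genes gave 0.193. The calls of Kcnj3 and Cox7a1 ended with the clusters of 2 types (0.0543 in a range from 2.18e-12, and 0.0765 in a range from 2.52e-07). That of Cox8b ended there and in nuclei of 4000 to 9000 UMIs (0.276 and 0.289 in a range from 4.41e-05). Kcnd2 ended without control mice 1 and 2 and homozygous mice 4, 5 and 6 (0.0699 to 0.134) in a range from 6.04e-05 to 0.219. Dpp4 gave 0.0514 to 0.150 without each of the control mice 1 to 3 and homozygous mice 4 to 6 in a range from 0.00389 to 0.295. Smoc2 gave 0.0658 in nuclei of 4000 to 9000 UMIs in a range from 3.54e-15.

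The other 18 lists did not pass in homozygous against control cardiomyocytes, beside gene lists 1 and 2. Adjusted p by camera was 0.711 for DNA damage response and repair (gene list 4), 0.635 for senescence (5), 0.758 for sarcomere (7), 0.102 for calcium handling (8). It was 0.977 for fatty acid oxidation (10), 0.367 for mitochondrial biogenesis (13), 0.711 for glycolysis (14), 0.367 for heat shock and unfolded proteins (16) and 0.481 for immediate early genes (17). It was 0.711 for interferon-stimulated genes (18), 0.290 for inflammatory genes (19), 0.481 for extracellular matrix (20), 0.641 for resident macrophages (22), 0.179 for recruited macrophages (23). It was 0.102 for capillary genes (24), 0.987 for cell cycle (25), 0.290 for apoptosis and necroptosis (26) and 0.641 for autophagy (27). Single members of such lists passed. Bcl2, an inhibitor of apoptosis, rose by 1.20 ± 0.22 and Bcl2l11, its antagonist, fell by 1.41 ± 0.33. Of the calcium handling list, Sorcs2, a sorting receptor, fell by 1.45 ± 0.25, and Casq2, which binds calcium in the sarcoplasmic reticulum, rose by 0.88 ± 0.19, at a list median of -0.20. Neb fell by 0.71 ± 0.15 (edgeR QL, BH-adjusted p = 0.00793, 0.0323, 0.00489, 0.0193 and 0.0193). Of the capillary list, Kdr fell by 0.79 ± 0.18 and Fabp4 by 0.79 ± 0.21 (0.0246 and 0.0483), and these stood at 181 and 2178 CPM in endothelial nuclei of homozygous and 210 and 2410 CPM in those of control mice. Bcl2 stood at 336 CPM in fibroblasts of homozygous and 241 CPM in those of control mice. The median, mean and test differed in sign for fatty acid oxidation (-0.07, 0.00 and lower), glycolysis (-0.06, 0.06 and higher) and cell cycle (0.02, 0.02 and lower). The calls of Bcl2 and Sorcs2 ended with the clusters of 2 types (0.458 and 0.0660). Kdr lost its call without control mice 1, 2 and 3 and homozygous mice 4, 5 and 6 (0.0561 to 0.0958), and Fabp4 without control mice 1, 2 and 3, homozygous mice 5 and 6 and heterozygous mouse 8 (0.0649 to 0.159). That of Casq2 ended without control mice 2 and 3 and homozygous mouse 5 (0.0719 to 0.0944), and that of Neb without control mouse 3 and homozygous mice 4, 5 and 6 (0.0557 to 0.0703). That of Bcl2l11 ended without control mice 1, 2 and 3 and homozygous mice 4 and 5 (0.0625 to 0.103). Over all alternatives Bcl2 ranged from 2.73e-09 to 0.458, Casq2 from 2.08e-05 to 0.0944, Neb from 0.00539 to 0.851, Bcl2l11 from 2.42e-12 to 0.103, Sorcs2 from 7.05e-13, Kdr from 0.0203 to 0.376 and Fabp4 from 5.42e-04 to 0.478.

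In heterozygous mice, with 1 Terf2 copy targeted, cardiomyocytes also had more Lrrtm4, Gpc5, Dpp10 and Ptgds RNA than in controls. Lrrtm4 stood at 32.4 ± 13.7 CPM, 5.26 ± 0.49 above control on the log2 scale, Gpc5, a cell surface proteoglycan, at 22.5 ± 8.67 CPM, 4.44 ± 0.49 above, and Dpp10 at 22.2 ± 4.20 CPM, 4.41 ± 0.31 above. Ptgds rose by 1.80 ± 0.30, to 552 ± 195 CPM, and Rhbdl3 fell by 1.02 ± 0.19, to 33.4 ± 2.40 from 67.8 ± 2.66 CPM. These passed with adjusted p = 2.77e-04, 0.00101, 2.78e-05, 0.0198 and 0.0356 (edgeR QL, BH). In all 50 of 13681 genes were called, 43 higher and 7 lower. Clcn1, at -1.12 (adjusted p = 0.0908), Ryr3, at 1.69 ± 0.48 (0.233), and Nrg1, at 1.14 ± 0.34 (0.249), did not pass here. By camera, 11 of the 27 lists passed, each with 0 members called over all genes and at least 0.364 estimated. Higher were p53 targets (median 0.35, adjusted p = 3.01e-05, 5 members over the list alone), oxidative phosphorylation (0.26, 1.21e-05, 2), recruited macrophage genes (1.22, 1.20e-05, 5). So were resident macrophage genes (0.63, 3.42e-04, 4), resting fibroblast genes (0.45, 4.43e-05, 6), extracellular matrix (0.44, 0.00121). Also higher were capillary genes (0.24, 0.0157, 4), the integrated stress response (0.51, 0.00913), senescence (0.32, 0.0430, 3) and immediate early genes (0.38, 0.0483). Channel genes were lower (median -0.22, adjusted p = 0.00863). The other 16 lists had adjusted p of at least 0.0581, among them cardiac stress genes at 0.390 with a median of 0.16 and a mean of -0.03. Markers of macrophages (median 0.85, adjusted p = 3.25e-05) and of fibroblasts (0.45, 0.00106) were also higher in these cardiomyocyte sums and markers of atrial cardiomyocytes lower (-1.44, 0.0240), with at least 0.502 estimated. The oxidative phosphorylation genes were higher in the other 5 types too, at medians of 0.42 to 0.48 with 30 of 30 members above 0 and 0 called in each, at least 0.167 estimated. The senescence list gave 0.0505 to 0.278 without control mice 1 and 2, homozygous mouse 6 and heterozygous mice 7 and 9, and 0.322 on thinned counts. Immediate early genes gave 0.305 without control mouse 1 or 2, 0.0505 without homozygous mouse 6, 0.723 without heterozygous mouse 7, where they turned lower, and 0.0951 without heterozygous mouse 8. The integrated stress response gave 0.0621 and 0.131 without control mouse 2 and heterozygous mouse 7, the channel genes 0.0621 without control mouse 2 and the capillary genes 0.115 without control mouse 3. The count of 50 became 29, 16 and 18 without control mice 1, 2 and 3, 29 without heterozygous mouse 8 and 92 without heterozygous mouse 9. It became 29 among nuclei of 4000 to 9000 UMIs and 123 with DESeq2. Ptgds ended without control mice 2 and 3 and heterozygous mouse 8 (adjusted p = 0.151, 0.113 and 0.0635, range 6.34e-19 to 0.151), Dpp10 in nuclei of 4000 to 9000 UMIs (0.0702, range from 2.84e-35). Rhbdl3 lost its call in 10 of 22 alternatives, without control mice 1, 2 and 3, homozygous mouse 6 and heterozygous mice 7, 8 and 9 (0.0534 to 0.188) among them.

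Of the 50 genes called in heterozygous mice 43 were also called in homozygous mice in the same direction, 37 higher and 6 lower, and 0 in the opposite direction (edgeR QL, BH, both against the same 3 controls). In 20 simulated draws of unchanged groups against shared controls, a test chosen after the result, the 561 and 50 genes of lowest p shared 22.75 on average and 16 to 29 in the same direction. Lrrtm4, Dpp10, Tenm2, Gpc5, Mgat4c, Galntl6, Cntnap2 and Ptgds were among the genes higher in both. Across the tested genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of 0.564, against 0.561 in the simulated draws, where r comes from the shared controls alone, and their covariance was 0.126 against 0.0474. Without control mice 1, 2 and 3 the shared genes numbered 29, 16 and 18, and without heterozygous mouse 8 they numbered 24. With DESeq2 76 were shared and 2 opposite.

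Against heterozygous mice, cardiomyocytes of homozygous mice had more natriuretic peptide and p53 target RNA and less RNA of the respiratory chain, of ribosomal proteins and of interstitial cells. Nppa stood at 1342 ± 680 against 214 ± 59.6 CPM, a rise of 2.65 ± 0.42. It rose in fibroblasts by 2.16 ± 0.43, endothelial nuclei by 2.46 ± 0.39 and pericytes by 2.25 ± 0.34 too (adjusted p = 0.0272, 0.0113 and 9.08e-04), with 1381 and 306 CPM in fibroblasts of homozygous and heterozygous mice. Pvt1 rose by 1.78 ± 0.15 from 43.3 ± 5.17 CPM, and Cd44, a hyaluronan receptor, by 1.88 ± 0.17, to 41.9 ± 3.47 from 11.4 ± 0.455 CPM. Nppb rose by 1.67 ± 0.24 and the glutamate receptor gene Gria3 by 2.20 ± 0.26, to 92.5 ± 11.6 from 20.5 ± 10.1 CPM. Cox8b fell by 1.42 ± 0.15, to 79.8 ± 8.92 from 213 ± 28.2 CPM, and H2-Aa, an antigen presentation gene of immune cells, by 2.03 ± 0.31. Their adjusted p values were 0.00388, 2.25e-04, 2.25e-04, 0.00262, 0.00162, 7.21e-04 and 0.00313 (edgeR QL, BH). In all 617 genes were called, 165 higher and 452 lower. Of the 30 oxidative phosphorylation genes 12 fell, 22 over the list alone, Cox7a1, Cox6c and Ndufa4 among them. They had a median of -0.54, camera adjusted p = 4.85e-21, 0.198 estimated and 0.0251 by fry. In the other 5 types the medians lay between -0.44 and -0.59 (at least 0.229 estimated). Cardiac stress genes were higher (3 of 19 called, Nppa, Nppb and Xirp1, 6 over the list alone, median 0.36, adjusted p = 3.94e-05, 0.220 estimated). So were p53 targets (Pvt1 and Gdf15, median 0.21, 0.00909, 0.392 estimated). Lower were resting fibroblast genes (7 of 16 called, Dcn among them, 11 over the list alone, median -0.99, 4.07e-11). So were recruited macrophage genes (4 of 7, Cd74 among them, median -1.71, 5.54e-08) and capillary genes (4 of 18, Fabp4 and Cxcl12 among them, median -0.55, 5.96e-05), each 0.198 estimated. Inflammatory genes (Ccl7, 0.0178), immediate early genes (0 called, 0.0178), mitochondrially encoded (0 called), resident macrophage (0 called) and autophagy genes (4 of 21 called), each 0.0337, were lower as well. With an estimated correlation these gave at least 0.392. Without homozygous mouse 5 these lists gave 0.0569, 0.291, 0.0569, 0.291 and 0.182, and on thinned counts inflammatory genes gave 0.266 and autophagy genes 0.0716. Without heterozygous mouse 7 immediate early, resident macrophage and autophagy genes gave 0.388, 0.401 and 0.241, and mitochondrially encoded genes gave 0.0596 without homozygous mouse 6 and 0.370 without heterozygous mouse 8. The other 16 lists had adjusted p of at least 0.156. Of 75 ribosomal protein genes, a list chosen after the data were seen, 55 fell at a median of -0.78 (camera adjusted p = 1.91e-60, 0.0869 estimated). They were lower in the other 5 types too, at medians of -0.19 in pericytes to -0.28 in endothelial nuclei (7.52e-08 at most, at least 0.150 estimated). Markers of fibroblasts, epicardial cells, macrophages and erythroid cells were lower in the same sums (adjusted p = 2.39e-04, 2.39e-04, 0.00279 and 0.0490, at least 0.483 estimated). Dcn stood at 1799 and 1734 CPM in fibroblasts of homozygous and heterozygous mice, Fabp4 at 2178 and 2919 CPM in endothelial nuclei, and Cd74 at 755 and 746 CPM in monocytes and dendritic cells. The count of 617 became 255 and 272 without homozygous mice 5 and 6, and 403 without heterozygous mouse 8. It became 17 among nuclei of 4000 to 9000 UMIs, 8 higher and 9 lower, and 70 with the clusters of 2 types. Nppa, Pvt1, Cd44 and Cox8b kept their calls in 22 of 22 alternatives. Nppb and Gria3 lost theirs with the clusters of 2 types (0.0506 and 0.124, ranges from 1.61e-19 and 1.70e-30), and H2-Aa lost it there and among nuclei of 4000 to 9000 UMIs (0.0661 and 0.0898, range from 2.10e-15). Xirp1 lost its call in 12 of 22 alternatives (range 0.0226 to 0.612), without control mice 1 and 2, homozygous mice 4, 5 and 6 and heterozygous mice 8 and 9 (0.0533 to 0.179) among them. Gdf15 lost it without homozygous mice 4 and 6 and heterozygous mouse 8 (0.0721, 0.0972 and 0.0944, range 6.21e-10 to 0.106). In nuclei of 4000 to 9000 UMIs or with the clusters of 2 types the other list members named lost theirs (0.0738 to 0.236). Nppa lost its call in fibroblasts without homozygous mice 4 and 6 and heterozygous mice 8 and 9 (0.0660 to 0.101).

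**Figure D2:**
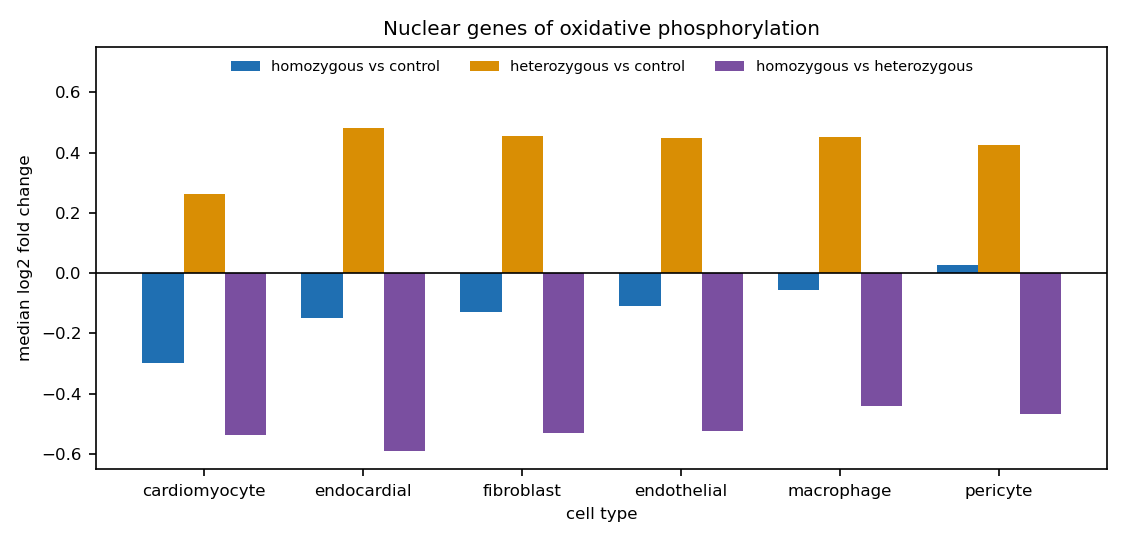
Median log2 fold change (y axis) of 30 nuclear genes of oxidative phosphorylation in 6 cell types (x axis), 1 bar per comparison. Between homozygous and heterozygous mice they lay between -0.44 in macrophages and -0.59 in endocardial nuclei.

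Over the 3 genotypes together 677 cardiomyocyte genes were called (edgeR QL, BH). This became 428 without control mouse 2, 424 and 362 without homozygous mice 5 and 6, 139 among nuclei of 4000 to 9000 UMIs and 313 with the clusters of 2 types.

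Cardiomyocyte nuclei of homozygous mice held 2.16-fold more RNA counts than those of controls, with a median of 9765 ± 838 UMIs per nucleus (SD, n = 3) against 4530 ± 174 in control and 3756 ± 441 in heterozygous mice. They held 3543 ± 140 genes against 2104 ± 72.3 and 1847 ± 236. The 3 homozygous mice stood above the other 6 in UMIs. Among the genotypes the exact permutation p was 0.00357 for UMIs, the smallest that 280 splits allow, and 0.00714 for genes, with BH-adjusted p = 0.0643 over 18 measures, so neither passed after adjustment. Between genotype pairs the exact two-sided p for UMIs was 0.1, the smallest possible. In the other types the ratio was 0.950 in fibroblasts, 0.976 in macrophages, 1.00 in pericytes, 1.02 in endocardial and 1.04 in endothelial nuclei.

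**Figure D3:**
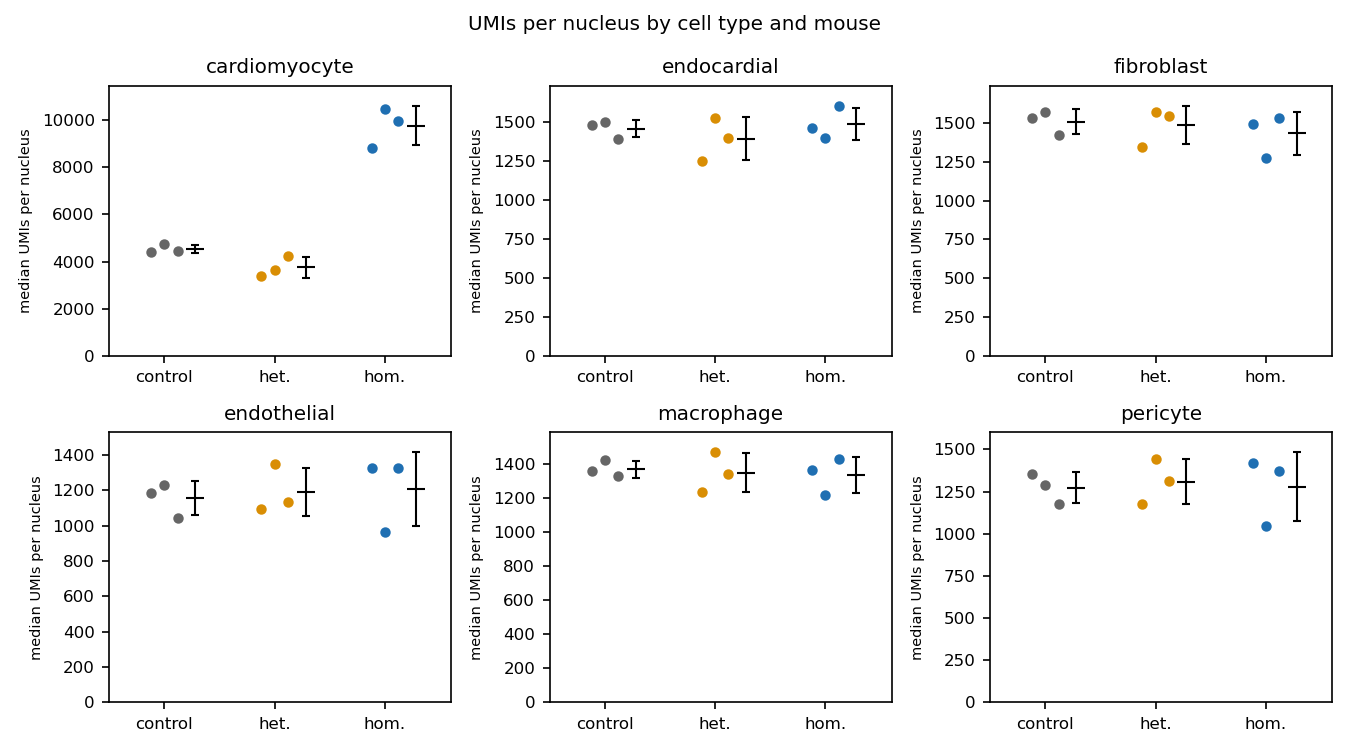
Median UMIs per nucleus (y axis) by genotype (x axis) in 6 cell types. Points are mice and bars mean ± SD of 3 mice, and cardiomyocytes of homozygous mice stood at 9765 ± 838 UMIs against 4530 ± 174 in controls.

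By the exact test of shares 0 of 15 types passed after adjustment, and 3 had an unadjusted p under 0.05. Macrophages were 10.9 ± 1.61% of named nuclei in heterozygous, 5.41 ± 1.56% in control and 5.57 ± 0.90% in homozygous mice (SD, n = 3, exact permutation p = 0.0321 over the 3 genotypes, BH-adjusted p = 0.161). Monocytes and dendritic cells were 1.47 ± 0.16%, 0.445 ± 0.077% and 0.902 ± 0.166% of nuclei in the same order, with the mice of each genotype apart from those of the others (exact p = 0.00357, adjusted p = 0.0536). Cardiomyocytes made up 12.6 ± 3.85% of nuclei in heterozygous, 7.24 ± 3.36% in control and 4.36 ± 0.53% in homozygous mice (exact p = 0.0321, adjusted p = 0.161). Fibroblasts (19.4 ± 3.38%, 24.6 ± 3.602% and 23.4 ± 6.11% in control, heterozygous and homozygous mice, exact p = 0.432) overlapped between genotypes. Endocardial nuclei made up 30.5 ± 11.2%, 19.7 ± 4.35% and 38.3 ± 6.79% in the same order (exact p = 0.0929). All homozygous mice stood above all heterozygous mice there (exact two-sided p = 0.1), and control mice overlapped with both. The first 3 types passed with edgeR (adjusted p = 0.0445, 0.0118 and 0.0450 in that order).

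**Figure D4:**
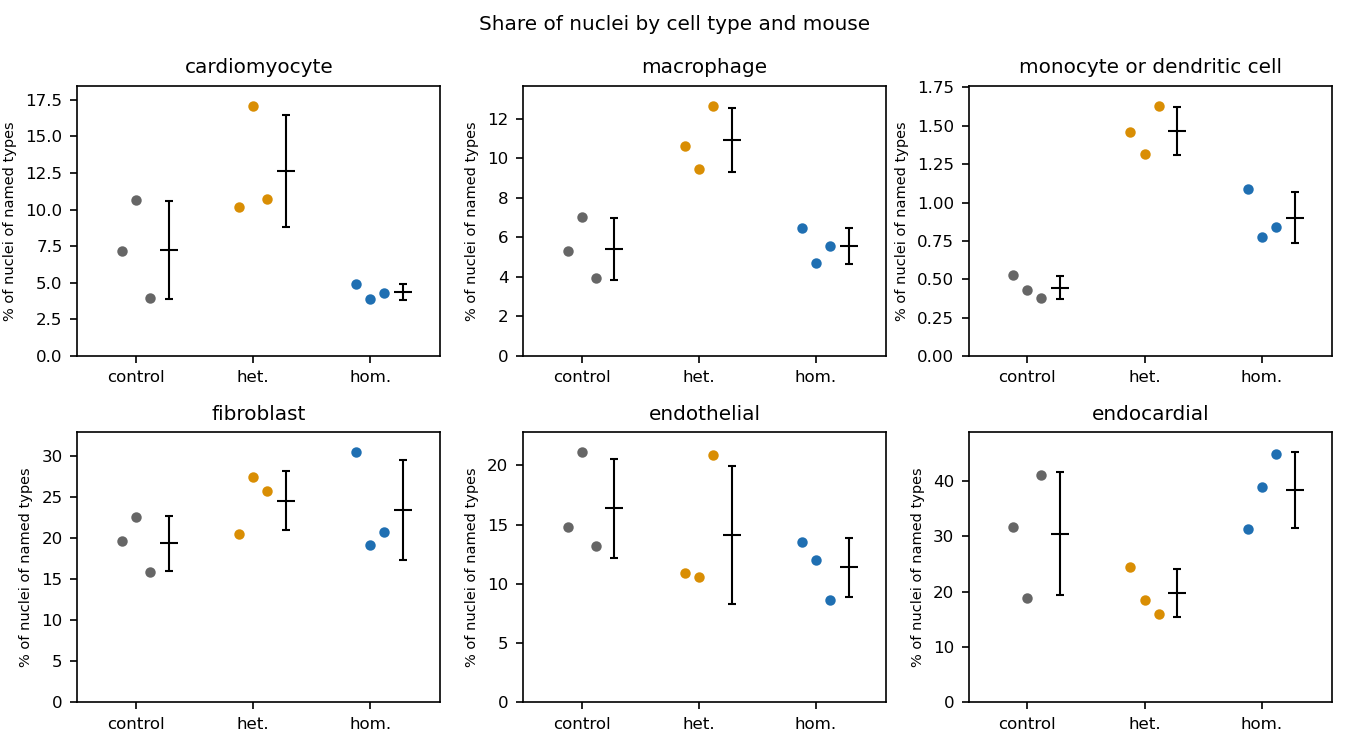
Share of named nuclei in % (y axis) by genotype (x axis) for 6 cell types. Points are mice and bars mean ± SD of 3 mice, and macrophages made up 10.9 ± 1.61% in heterozygous against 5.41 ± 1.56% in control mice.

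Endocardial nuclei, which line the heart chambers, were compared to learn whether cells next to the targeted muscle differed. In homozygous mice Otogl rose by 3.62 ± 0.32, to 271 ± 66.2 from 22.98 ± 8.94 CPM, and Sema3e, a guidance factor, by 3.27 ± 0.37, to 66.4 ± 24.4 from 7.29 ± 3.14 CPM. Kdr, a receptor for vascular endothelial growth factor, fell by 0.97 ± 0.13, to 45.1 ± 4.41 from 87.8 ± 6.25 CPM (edgeR QL, BH-adjusted p = 4.39e-04, 9.34e-04 and 0.00238). In all 227 of 13731 genes were called, 139 higher and 88 lower, Aff2 and Tuft1 among the rises. The falls included Sln and other atrial muscle genes, which stood at 88.3 CPM for Sln in atrial cardiomyocytes of homozygous and 665 CPM in those of control mice. Of 3 lists tested, p53 targets were higher (0 called, 5 over the list alone, camera adjusted p = 0.00291, 0.2499 estimated, as in the last value of the brackets on lists below). Extracellular matrix genes were also higher (4 over the list alone, 0.00291, 0.686), while capillary genes gave 0.112. Cardiomyocyte markers were higher and atrial and epicardial markers lower (3.67e-04, 1.23e-04 and 3.98e-05, at least 0.410). In heterozygous mice 3 genes were called. Prox1, a regulator of lymphatic and venous endothelium, was lower by 1.49 ± 0.19, at 45.2 ± 5.49 against 126 ± 21.7 CPM, and Tyrobp, a myeloid gene, was higher by 1.45 ± 0.21 (adjusted p = 0.0197 and 0.0486). Myh7 was higher as well, and stood at 714 CPM in heterozygous and 464 CPM in control cardiomyocytes. Markers of macrophages were higher in these sums (adjusted p = 1.91e-08, 0.258), also of cardiomyocytes, fibroblasts and monocytes, and atrial markers lower (9.00e-07 to 0.00495, at least 0.272). The p53 targets (0.0134, 0.302) and capillary genes (0.0106, 0.373) were higher as well. Between homozygous and heterozygous mice 193 genes were called, 107 higher and 86 lower. Dlgap1 was up by 3.01 ± 0.34 and Otogl up by 2.89 ± 0.31 (adjusted p = 0.00167 and 0.00144). Capillary genes were lower (3 of 18 called, Fabp4, Cxcl12 and Gpihbp1, median -0.44, camera adjusted p = 1.13e-04, 0.431). Markers of pericytes, macrophages, monocytes and epicardial cells were lower in the same sums and endocardial markers higher (3.04e-04 to 0.0285, at least 0.272). Endocardial nuclei fell into 3 clusters, of which cluster 1 held 71.3 ± 2.81% of them in control, 74.0 ± 6.27% in heterozygous and 38.2 ± 7.47% in homozygous mice. Cluster 7 held 7.96 ± 6.60%, 14.95 ± 8.97% and 42.7 ± 13.2%. Within cluster 1 alone 80, 23 and 59 genes were called in the 3 comparisons. The 227 calls became 94 and 91 without control mice 1 and 3, and 146 and 53 without homozygous mice 4 and 6. The 193 calls became 96 and 120 without control mice 1 and 2, 127, 55 and 53 without homozygous mice 4, 5 and 6, and 64 without heterozygous mouse 8. The 3 calls became 0 without control mouse 3 or heterozygous mouse 8, 1 without heterozygous mouse 7, and 8, 34 and 6 without homozygous mice 4, 5 and 6. Prox1 lost its call without control mouse 3 and heterozygous mice 7 and 8 (0.116, 0.0707 and 0.0966). Tyrobp lost it without control mice 1, 2 and 3 and heterozygous mice 7, 8 and 9 (0.0707 to 0.218). Fabp4, Cxcl12 and Gpihbp1 lost theirs without control mice 1 and 2, homozygous mice 5 and 6 and heterozygous mice 8 and 9, and Gpihbp1 also without heterozygous mouse 7 (adjusted p from 0.0520 to 0.156).

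Fibroblasts showed matrix and activation genes higher in homozygous mice. Meox1, a transcription factor of fibroblast activation, rose by 1.51 ± 0.25, to 40.2 ± 5.99 from 14.03 ± 3.21 CPM. Ccn2, a matricellular growth factor, rose by 1.25 ± 0.22, to 203 ± 52.2 from 85.7 ± 3.91 CPM, and Adamtsl2 by 2.09 ± 0.38 (edgeR QL, BH-adjusted p = 0.0448, 0.0448 and 0.0495). Cmah fell by 1.71 ± 0.22, to 10.4 ± 1.38 from 34.1 ± 7.23 CPM (adjusted p = 0.0103). Of 13837 genes 28 were called, 17 higher and 11 lower, against 1340 at an unadjusted p under 0.05. The extracellular matrix and activation list had 2 of 29 members called, and 12 higher and 1 lower over the list alone. It had a median of 0.47 and camera adjusted p = 1.03e-14, 0.104 estimated. The p53 targets were higher with 0 members called and 1 over the list alone (0.00659, 0.176 estimated). Of 13 marker lists 9 passed in these sums. Markers of cardiomyocytes, fibroblasts and macrophages were higher, and those of atrial cardiomyocytes, epicardial cells, pericytes, smooth muscle, adipocytes and erythroid cells lower (adjusted p from 7.86e-08 to 0.0437, at least 0.217 estimated). Senescence gave 0.718, with a median of -0.07 and a mean of 0.11, and resting fibroblast genes 0.793. Sln and Myl7 were among the falls and Nrg1 and Ankrd1 among the rises. Their highest levels lay in atrial cardiomyocytes (Sln 88.3 CPM in homozygous and 665 CPM in control mice, Myl7 238 and 1493 CPM), endocardial nuclei (Nrg1 5488 and 1280 CPM) and cardiomyocytes (Ankrd1 754 and 367 CPM). The 28 calls became 2, 4 and 16 without control mice 1, 2 and 3, 2, 75 and 2 without homozygous mice 4, 5 and 6, and 56, 4 and 61 without heterozygous mice 7, 8 and 9. Meox1 and Ccn2 lost their calls without control mice 1 and 2, homozygous mice 4 and 6 and heterozygous mouse 8 (adjusted p from 0.0702 to 0.206, and from 1.59e-11 for Meox1 and 1.68e-12 for Ccn2 over all alternatives), and Ccn2 also without control mouse 3 (0.113). Adamtsl2 lost it without control mice 1, 2 and 3, homozygous mice 4 and 6 and heterozygous mouse 8 (0.0824 to 0.223), and Cmah without homozygous mice 4 and 6 (0.0690 and 0.0681).

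In fibroblasts of heterozygous mice the potassium channel gene Kcnq5 fell by 2.94 ± 0.39, to 9.94 ± 2.66 from 75.4 ± 24.4 CPM, and Dkk3, a secreted Wnt pathway protein, fell by 1.82 ± 0.28 (edgeR QL, BH-adjusted p = 0.0180 and 0.0406). The macrophage genes Lyz2 and C1qc rose by 1.33 ± 0.22 and 1.18 ± 0.19 (adjusted p = 0.0419 each), beside macrophage markers as a list (8.15e-07, 0.116 estimated). Markers of cardiomyocytes, lymphatic endothelium and monocytes were higher too, and those of atrial cardiomyocytes and smooth muscle lower (2.26e-06 to 0.0156, at least 0.116 estimated). The count was 15, 7 higher and 8 lower. The lists gave adjusted p = 0.0354 for senescence (higher, 1 member over the list alone, 0.288 estimated), 0.128 for p53 targets, 0.275 for extracellular matrix and 0.144 for resting fibroblasts. Between homozygous and heterozygous mice 191 genes were called, 97 higher and 94 lower. L3mbtl4 rose by 2.32 ± 0.29, to 43.9 ± 15.8 from 8.82 ± 1.61 CPM (adjusted p = 0.00839). Ltbp2 rose by 1.91 ± 0.32, Meox1 by 1.37 ± 0.24 and Col5a2 by 0.59 ± 0.12, while Dpp4 fell by 1.17 ± 0.22 (adjusted p = 0.0154, 0.0156, 0.0368 and 0.0204). The matrix list had 5 of 29 members called, and 13 higher and 2 lower over the list alone. Its median was 0.47 and adjusted p = 1.43e-07, 0.295 estimated. Fibroblast markers were higher there, and markers of atrial cardiomyocytes, pericytes, macrophages, monocytes and epicardial cells lower (0.00117 to 0.0340, at least 0.169 estimated). The other lists gave 0.336 for p53 targets, 0.207 for senescence and 0.176 for resting fibroblasts, whose median of 0.04 and mean of -0.24 differed in sign. The 15 calls became 0, 2 and 0 without control mice 1, 2 and 3, 31, 50 and 5 without homozygous mice 4, 5 and 6, and 7 and 0 without heterozygous mice 7 and 9. Kcnq5 and Dkk3 lost their calls without control mice 1, 2 and 3 and heterozygous mouse 9, and Dkk3 also without heterozygous mouse 8 (0.0632 to 0.137). Lyz2 and C1qc lost theirs without control mice 1, 2 and 3, homozygous mouse 6 and heterozygous mice 7 and 9, and Lyz2 also without heterozygous mouse 8 (0.0606 to 0.174). The 191 calls became 80, 87 and 54 without homozygous mice 4, 5 and 6, and 90 and 117 without heterozygous mice 8 and 9. Ltbp2 lost its call without heterozygous mouse 8 (0.0503), and Meox1 and Dpp4 without homozygous mouse 4 (0.0539 and 0.0564). Dpp4 lost it also without homozygous mouse 6 and heterozygous mouse 9 (0.0938 and 0.0511), and Col5a2 without control mouse 1, homozygous mice 4, 5 and 6 and heterozygous mice 7, 8 and 9 (0.0679 to 0.111).

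Whether the change from control to homozygous mice differed between cardiomyocytes and fibroblasts was tested with an interaction in edgeR. It differed for 342 of 15064 genes, 135 higher and 207 lower in cardiomyocytes, of which 177 were among the 559 genes called in cardiomyocytes. The count became 160, 107 and 151 without control mice 1, 2 and 3, and 174 and 145 without homozygous mice 4 and 6. Of the 7 p53 targets called in cardiomyocytes the change differed for Pvt1, by 2.50 ± 0.18, and Zmat3, by 1.10 ± 0.24 (BH-adjusted p = 1.66e-06 and 0.0235), and not for Cdkn1a, Gdf15, Phlda3, Perp or Trp53cor1. Of the 7 stress genes it differed for Myh7, by -1.61 ± 0.27, which rose by 0.97 in cardiomyocytes and by 2.60 in fibroblasts (adjusted p = 0.00472). It stood at 96.3 and 15.98 CPM in fibroblasts of homozygous and control mice, and free RNA and expression were not separated there.

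Endothelial nuclei of homozygous mice had fewer differences from control, 13 of 11587 genes, 8 higher and 5 lower (edgeR QL, BH). Hlf, a clock-controlled transcription factor, fell by 1.27 ± 0.22, to 32.6 ± 5.05 from 79.0 ± 10.3 CPM (adjusted p = 0.0319). Nrg1, Acta1, Nppb and Ankrd1 were among the rises and Sln, Myl7 and Myl4 among the falls. Their highest levels lay in endocardial nuclei and muscle, with Myl4 at 425 CPM in atrial cardiomyocytes of homozygous and 2129 CPM in those of control mice. Atrial cardiomyocyte markers were lower in these sums (camera adjusted p = 3.67e-15, 0.0351 estimated), as were those of pericytes, epicardial and erythroid cells, and cardiomyocyte markers higher (2.45e-07 to 0.0138, at least 0.168 estimated). The p53 targets were higher with 0 members called and 1 of 22 over the list alone (0.0148, 0.453 estimated). Inflammatory genes gave 0.0532 and capillary genes 0.766. In heterozygous mice 19 genes were called, all 19 higher. The antigen presentation gene H2-Eb1 was up by 1.70 ± 0.25, to 58.1 ± 21.5 from 18.4 ± 2.48 CPM, and H2-Aa was up by 1.67 ± 0.30 (adjusted p = 0.0136 and 0.0369). Macrophage markers were higher there (4.77e-09, 0.0742 estimated), also those of cardiomyocytes, fibroblasts and pericytes, and atrial and endothelial markers lower (4.79e-10 to 0.0263, at least 0.135 estimated). The 3 lists gave 0.387 each. Between homozygous and heterozygous mice 75 genes were called, 20 higher and 55 lower. Gja5, an arterial gap junction gene, rose by 1.56 ± 0.29, to 43.3 ± 13.7 from 15.5 ± 5.55 CPM, and H2-Eb1 and Cd74 fell by 2.13 ± 0.28 and 1.67 ± 0.23 (adjusted p = 0.0241, 0.00626 and 0.00626). Markers of pericytes (8.47e-07, 0.110 estimated), macrophages (7.67e-04, 0.238), fibroblasts, atrial cardiomyocytes and epicardial cells were lower and endocardial ones higher (up to 0.00597, 0.295 each). The 3 lists gave 0.287, 0.417 and 0.417. The 13 calls became 4, 1 and 7 without control mice 1, 2 and 3, 6, 34 and 1 without homozygous mice 4, 5 and 6, and 31 without heterozygous mouse 9. With at most 5% mitochondrial UMIs 0 genes were called in each comparison, but only 2 of the 13, 1 of the 19 and 29 of the 75 had a value there. Hlf lost its call without control mice 1, 2 and 3 and homozygous mice 4 and 6 (adjusted p from 0.0728 to 0.256). The 19 calls became 3, 2 and 2 without control mice 1, 2 and 3, 34 and 10 without homozygous mice 5 and 6, and 33 without heterozygous mouse 9. The 75 calls became 13 and 8 without homozygous mice 5 and 6, and 39 and 25 without heterozygous mice 8 and 9. H2-Eb1 and H2-Aa lost their calls against control without control mice 1, 2 and 3 (0.0703 to 0.244), and H2-Aa without heterozygous mouse 9 (0.0533). Against heterozygous mice Gja5 lost it without homozygous mice 5 and 6 and heterozygous mouse 9 (0.105, 0.102 and 0.0827). H2-Eb1 and Cd74 kept theirs in the 18 alternatives that gave them a value, and had none with at most 5% mitochondrial UMIs.

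Pericytes, which wrap capillaries, had 18 of 6135 genes called between homozygous and control mice, 12 higher and 6 lower (edgeR QL, BH). Dbp, a clock-controlled transcription factor, fell by 1.72 ± 0.35, to 63.7 ± 19.4 from 210 ± 97.5 CPM (adjusted p = 0.0131). The others named were Nrg1, Acta1, Ankrd1 and Nppb, higher, and Myl4, Myl7 and Sln, lower. Myl4 was down by 2.88 ± 0.37, to 33.7 ± 23.9 from 246 ± 106 CPM (4.03e-05), and atrial cardiomyocytes held 425 CPM in homozygous and 2129 CPM in control mice. In heterozygous mice 4 genes were called, Myl4 lower by 2.25 ± 0.31 and the macrophage genes C1qb and Lyz2 and the muscle gene Myh7 higher (1.75e-04 for Myl4, 0.0305 for C1qb and Lyz2 each). Between homozygous and heterozygous mice 16 genes were called, 6 higher and 10 lower. Eya4, a transcription factor, rose by 1.78 ± 0.31, to 157 ± 21.7 from 48.3 ± 29.2 CPM, and Aldh1a1, a retinoic acid enzyme of epicardial cells, by 1.49 ± 0.27, while Clec3b, a fibroblast gene, fell by 1.86 ± 0.39 (adjusted p = 0.00310, 0.00565 and 0.0176). The p53 targets gave adjusted p = 0.550, 0.186 and 0.803 and extracellular matrix 0.344, 0.800 and 0.522 in the 3 comparisons. The 18 calls became 9 without control mouse 3, 7 without homozygous mouse 6, and 38 and 39 without heterozygous mice 7 and 9. With at most 5% mitochondrial UMIs 0 were called in each comparison, but only 2 of the 18, 0 of the 4 and 1 of the 16 had a value there. The 4 calls became 1, 1, 9, 11, 13 and 16 without control mice 1 and 2, homozygous mice 4 and 5 and heterozygous mice 7 and 9. The 16 calls became 4 without homozygous mouse 6 and 26 without heterozygous mouse 7. Dbp lost its call without control mouse 3 and homozygous mouse 6 (adjusted p = 0.0966 and 0.189), C1qb and Lyz2 without control mice 1 and 2 and heterozygous mouse 9 (0.0794 to 0.279). Aldh1a1 lost its call without homozygous mouse 6 and heterozygous mouse 8 (0.125 and 0.0675) and Clec3b without homozygous mice 4, 5 and 6 (0.0603 to 0.111).

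Macrophages had the fewest calls and shifted in their lists between the targeted genotypes. Epha7 was higher in homozygous than in heterozygous mice by 1.83 ± 0.26, at 57.0 ± 19.6 against 16.2 ± 1.65 CPM, the 1 call of 9880 genes there (edgeR QL, BH-adjusted p = 0.0308). It also marks endocardial cluster 7, so free RNA stays open. The 1 call between homozygous and control mice was Myh7, higher, with 920 CPM in homozygous and 464 CPM in control cardiomyocytes. Between heterozygous and control mice 0 genes were called by edgeR and 1 by DESeq2, and 827 had an unadjusted p under 0.05. Interferon-stimulated genes were higher in homozygous than in heterozygous macrophages, with a median of 0.46 and 24 of 26 members above 0. There 1 member passed over the list alone, with camera adjusted p = 1.11e-08, 0.204 estimated, which is the last value in each bracket below. They were higher than in control (0.0116, 0.666) and lower in heterozygous than in control mice (0.00343, 0.442). Resident macrophage genes were higher in homozygous than in heterozygous mice (median 0.46, 6 of 12 over the list alone, adjusted p = 3.07e-06, 0.0628) and lower in heterozygous than in control mice (0.00228, 0.213), with 0.156 between homozygous and control. Recruited macrophage genes were higher in heterozygous than in control mice (0.00426, 0.442) and lower in homozygous than in heterozygous mice (0.00212, 0.434), with 0.740 between homozygous and control, where the median of -0.14 and the mean of 0.22 differed in sign. Inflammatory genes gave 0.506, 0.705 and 0.270. The count of 1 between homozygous and control mice became 0 without control mice 1, 2 or 3 or heterozygous mouse 8 and with at most 5% mitochondrial UMIs, 8, 12 and 9 without homozygous mouse 5 and heterozygous mice 7 and 9. Epha7 lost its call without control mice 1, 2 and 3, homozygous mice 4 and 6 and heterozygous mouse 8 (0.0513 to 0.283). The count was 3, 22, 3 and 11 without homozygous mouse 5 and heterozygous mice 7, 8 and 9.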

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

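The test of the difference between cardiomyocytes and fibroblasts, the tests of free RNA for the p53 targets and the shared genes, the comparison of the shared genes with matched genes, and the test of free RNA that differed between the libraries were chosen after the results had been seen. A difference between these types in the change from control to homozygous mice was found by an interaction test in edgeR for 342 genes. Without control mice 1, 2 and 3 or homozygous mice 4 and 6 it was 107 to 174. Among the p53 targets it held for Pvt1, at 2.50 (BH-adjusted p = 1.66e-06), and for Zmat3, at 1.10 (adjusted p = 0.0235). Among the cardiac stress genes it held for Myh7, at -1.61 (adjusted p = 0.00472). Myh7 stood at 96.3 CPM in fibroblasts, 116 CPM in macrophages and 920 CPM in cardiomyocytes of homozygous mice, so its change in fibroblasts was not told apart from that of free muscle RNA and is not read as a difference in expression between the types. Of the 10 splits of the mice the real 1 gave 342 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

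The p53 targets that rose in cardiomyocytes of homozygous mice could have come with free RNA or with the deeper counts of these nuclei. Pvt1 alone, 1 of 7, rose by more in cardiomyocytes than in any of 5 other types by over 2 standard errors, at 127 ± 13.6 CPM against 14.7 ± 43.8 CPM in macrophages, which argues against free RNA for that gene. For the remaining genes, 6 of 7 with Cdkn1a and Gdf15 among them, free RNA stays open. Among nuclei of 4000 to 9000 UMIs the median log2 fold change of the 7 genes was 1.07 times that in all nuclei, which argues against more RNA counted per nucleus. A response of heart muscle to loss of TRF2 is left open by these values, since Terf2 itself did not pass and the deletion was not checked.

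Oxidative phosphorylation genes were lower in cardiomyocytes of homozygous than of heterozygous mice, and about as low in other cells. The lower ratio of the median change in fibroblasts and in endothelial nuclei to that in cardiomyocytes was 0.972, which is what free RNA that differed between the libraries would give. A change in cardiomyocytes alone is argued against by the level in cardiomyocytes less that in fibroblasts of the same mouse, which differed by -0.0161 between the genotypes (exact permutation p = 0.6). Among nuclei of 4000 to 9000 UMIs the median change was 0.544 times that in all nuclei, so free RNA diluted in deeper nuclei stays open. A change shared by all cell types of the heart would give the same values and was not told apart from free RNA.

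The 37 genes called higher in cardiomyocytes of both heterozygous and homozygous mice, Lrrtm4, Dpp10 and Tenm2 among them, could reflect another type or a bias. In CPM 25 of them rose more in cardiomyocytes than in any of 5 other types by over 2 standard errors in both genotypes, which argues against free RNA for these, and for the remaining 12 it stays open. Nuclei of another type stay open. In another cluster 29 of 37 were higher, but so were 326 of 337 genes of like length and level. Lower atrial markers in these sums cannot decide this, as homozygous atrial nuclei had more Tenm2 and less Sln than control. Other genes of like length and level had median log2 fold changes of 0.16 in homozygous and 0.24 in heterozygous mice. The set had 3.25 and 3.16, which gave a ratio of 0.0761 at most. Over all tested genes the medians were 0.00041 and 0.016. The 37 genes were chosen for their rise, so this ratio cannot decide on a bias with gene length, which stays open. More RNA counted per nucleus is argued against by a ratio of 0.913 among nuclei of 4000 to 9000 UMIs for the 31 with a value there. For the other 6 it stays open. An effect of the targeted allele or of its background in muscle stays open, since the labels give no breeding or batch, and shared controls alone gave 16 to 29 shared genes in simulated draws, against 43.

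Grouping was tested by refitting with genotypes exchanged, and 10 splits allow no share under 0.05. In cardiomyocytes the real grouping was the 1 of 10 with the most calls in each comparison, at 561, 50 and 617 genes against 0, 1 and 0 in the highest other. It was also 1 of 10 in endocardial nuclei (highest others 0, 0 and 0), fibroblasts (1, 0 and 0) and endothelial nuclei (1, 3 and 4). In pericytes 1, 3 and 1 splits reached the real counts of 18, 4 and 16, with highest others of 3, 12 and 0. In macrophages 2, 10 and 2 splits reached the real counts of 1, 0 and 1, with highest others of 1, 5 and 1. Over 3 genotypes of cardiomyocytes the real grouping was the 1 of 100 with the most calls, 677, so chance is unlikely. The next, at 257, also kept the homozygous mice together, so this tests mostly that group.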

How the results depend on the processing

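Several alternatives, listed above, were chosen after seeing the data. Of 22 alternatives the count of cardiomyocyte calls stayed within 1.5 times the main count in 15 between homozygous and control, 14 between heterozygous and control and 14 between homozygous and heterozygous mice. Of the values of named genes called in the first fit, 3315 of 4041 kept direction and side of the threshold, 725 lost the threshold and 1 turned. In cardiomyocytes at most 12, 1 and 2 called genes turned direction in any setting of the 3 comparisons. The median UMIs per cardiomyocyte nucleus kept a log2 ratio of 0.81 to 1.18. A sex term was not run since all mice were male, and no pairing was possible.

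Counts below are in the order homozygous with control, heterozygous with control and homozygous with heterozygous mice, and the cause was not tested unless named. Without the low-count filter, where more genes were tested, cardiomyocytes gave 1186, 528 and 1365 calls and 1969 over the 3 genotypes, endocardial nuclei 763, 645 and 910, and fibroblasts 477, 497 and 861. Endothelial nuclei gave 162, 174 and 321, macrophages 79, 93 and 159 and pericytes 43, 35 and 33. With DESeq2 the calls moved in cardiomyocytes to 123 in heterozygous mice and 1077 over the 3 genotypes, in endocardial nuclei to 342, 90 and 374 and in fibroblasts to 119, 102 and 357. They moved to 29 and 118 in endothelial nuclei of homozygous mice against control and heterozygous mice, to 11, 1 and 19 in macrophages, and to 10 and 1 in pericytes against control.

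Among cardiomyocytes of 4000 to 9000 UMIs, with fewer nuclei, the calls were 164, 29 and 17, and 139 over the 3 genotypes. With the clusters of 2 types they were 70 between homozygous and heterozygous mice and 313 over the 3 genotypes, and with the haemoglobin cluster 381 between homozygous and heterozygous mice. With only the 6 mice compared they were 394 for cardiomyocytes and 117 for endocardial nuclei of homozygous and heterozygous mice, 29 for endocardial nuclei of heterozygous and control mice, 61 and 40 for fibroblasts against control, 23 and 32 for endothelial nuclei of homozygous mice, 14, 1 and 0 for macrophages and 29 for pericytes of homozygous and control mice. In endocardial cluster 1 alone they were 80, 23 and 59. Without genes from other cells 1 call was left in endocardial nuclei of heterozygous mice and 0 in macrophages of homozygous and control mice.

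With at most 5% mitochondrial UMIs the calls were 22 in endocardial nuclei of heterozygous and control mice, 87 in fibroblasts of homozygous and heterozygous mice, 0, 0 and 0 in endothelial nuclei, 0, 3 and 2 in macrophages and 0, 0 and 0 in pericytes, by edgeR. With the limit of 10% there were 901, 1121 and 1436 endothelial and 455, 545 and 560 pericyte genes at an unadjusted p under 0.05. With at least 1000 UMIs the calls were 3 in fibroblasts of heterozygous mice, and 20 in endothelial nuclei and 31 in pericytes of homozygous mice, each against control. On counts thinned to the smallest library they were 14 in endocardial and 8 in endothelial nuclei of heterozygous and control mice, and 4 and 6 in macrophages of homozygous mice. With doublets kept and with the expected doublet rate pericytes of heterozygous and control mice gave 7 and 7.

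Terf2 turned direction without passing among nuclei of 4000 to 9000 UMIs, at 0.0398 against control and 0.14 against heterozygous mice in homozygous mice, and with at most 5% mitochondrial UMIs, at 0.0207 against heterozygous mice. Kdr in cardiomyocytes of homozygous against heterozygous mice turned to 0.0457 with the clusters of 2 types (adjusted p = 0.917). With edgeR 3 cell type shares passed, and 1 with nuclei other than cardiomyocytes as denominator. Of 29 gene lists past the threshold by camera in cardiomyocytes, 0 passed with an estimated correlation and 5 by fry. With DESeq2 76 genes were shared by heterozygous and homozygous cardiomyocytes.

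Leaving out 1 mouse at a time, the calls in cardiomyocytes ranged from 274 to 799, 16 to 92 and 255 to 639, and from 362 to 910 over the 3 genotypes. They ranged from 53 to 284, 0 to 34 and 53 to 232 in endocardial nuclei, 2 to 75, 0 to 50 and 54 to 244 in fibroblasts, and 1 to 34, 2 to 34 and 8 to 94 in endothelial nuclei. They ranged from 0 to 12, 0 to 1 and 0 to 22 in macrophages and 7 to 39, 1 to 16 and 4 to 26 in pericytes. Terf2 ranged from -0.22 to 0.00787 (without heterozygous mouse 8) in heterozygous against control and from -0.15 to 0.0797 (without homozygous mouse 4) in homozygous against heterozygous mice. Terf2 in cardiomyocytes less other nuclei ranged from -0.0485 to 0.11 between homozygous and control mice. The shared genes ranged from 16 to 53 and the genes that differed between cardiomyocytes and fibroblasts from 107 to 419.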

Other observations

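Lists of clock genes were chosen after the data were seen. In homozygous mice genes driven by the clock factors Arntl and Clock were lower than in controls in several cell types. In cardiomyocytes 6 of 12 fell, Dbp, Tef, Hlf, Per3, Nr1d2 and Ciart, 7 when adjusted over the list alone, at a median of -0.77 (camera adjusted p = 8.97e-09, and 0.0315 with an estimated correlation, the last value in the brackets below). In endocardial nuclei 5 of 12 fell at a median of -0.73 (3.44e-13, 0.0434). The medians were -0.49 in endothelial nuclei, where Hlf fell, -0.53 in pericytes, where Dbp and Hlf fell, and -0.32 in fibroblasts, where 0 of 12 were called by edgeR and 3 passed adjusted over the list alone (camera adjusted p = 5.00e-11, 2.59e-05 and 6.79e-04, then 0.0262, 0.0138 and 0.0198). In macrophages the list did not pass (0.107).

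Genes repressed by Nr1d1 and Nr1d2 were higher in homozygous mice in endocardial nuclei, where Arntl rose, at a median of 0.71 (0.00202, 0.0434), and in fibroblasts (6.79e-04, 0.0198), endothelial nuclei (0.00128, 0.0717) and cardiomyocytes (0.00562, 0.183). In cardiomyocytes of heterozygous mice the driven genes had a median of -0.36 (1.51e-05, 0.0977), and they were lower in 4 other types too (7.79e-04 to 0.0305, at least 0.151). The labels give no hour of collection for any mouse.

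Genes of ribosomal proteins, also a list chosen after the data were seen, had a median of 0.36 in cardiomyocytes of heterozygous against control mice, with 74 of 75 above 0 and 0 called by edgeR (camera adjusted p = 2.20e-18, 0.267), and were higher in the other 5 types (6.47e-11 at most, at least 0.160). In homozygous against control mice 11 of 75 fell in cardiomyocytes at a median of -0.43 (3.19e-21, 0.183), and other types did not pass (0.0653 to 0.818). Myh7 stood at 15.98, 70.2 and 96.3 CPM in fibroblasts of control, heterozygous and homozygous mice and at 16.6, 74.5 and 116 CPM in macrophages.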
